A study of Mus musculus with 2 samples.

How the data were processed

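The study profiled single cells sorted from the ischemic brain of Foxp3Egfp mice, which carry a green fluorescent reporter at the gene of the regulatory T cell factor Foxp3. There was 1 group with 2 replicate libraries, here called replicate 1 and replicate 2. Per the labels' protocols, mice aged 6 to 8 weeks were perfused with PBS and CD45+CD11b+CD3-F4/80+ cells were collected on a FACSAria sorter. Libraries were made with the Chromium 3' v3 kit, which counts captured transcripts by unique molecular identifiers (UMIs). The labels also state that barcoded cDNA of mice with stroke was combined for sequencing. They do not say that the replicates are separate animals, so p-values may measure technical spread only. The design text calls the cells infiltrated macrophages and speaks of a low sorting signal without naming the marker that was low.

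The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 4 per the file headers. They list every barcode of the kit, so cells had to be called here. The submitters' processing notes name STAR 2.5.1b, Cell Ranger 4.0.0 and Seurat 4, and the builds GRCm38, mm10 and GRCh38 without a role for each. The role of GRCh38 is not given in the sources used here, and neither is the treatment of reads shared by near-identical genes, so Hspa1a and Hspa1b, the H2 genes and the Ifit genes may share reads. Coordinates are 1-based and come from the GENCODE vM21 annotation of GRCm38, which holds 99.9% of the gene IDs in the files.

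The libraries held 101893367 UMIs (replicate 1) and 62850768 UMIs (replicate 2). Barcodes were kept as cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 15050 and 7910 cells. Scrublet, run per library through scanpy 1.11.5 with an expected 0.8% doublets per 1000 cells, marked 1426 cells (9.48%) of replicate 1. In replicate 2 it marked none of 7910 cells, which counts as a failed call under the rule set beforehand, and the 501 top-scoring cells (6.33%) were removed instead. Clustering used 13624 and 7409 cells holding 78812872 and 52351777 UMIs. Barcodes under 100 UMIs served as the profile of free RNA and held 4.91% and 4.40% of all UMIs.

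Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen per library without the function lists, mitochondrial genes and ribosomal protein genes, scaled to a maximum of 10, and reduced to 30 principal components (scikit-learn 1.9.0). Cells were grouped by a graph of 15 neighbours and Leiden clustering at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9), with no batch correction and a fixed seed of 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

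Clusters were named from 16 marker lists. The markers, function lists, cell filters, tests and the rule for named genes were fixed before the data were examined. The scoring rule that turns markers into names was written after the clusters had been seen. It took the 10 leading genes of a cluster, ranked by the lower of the 2 libraries' folds against the other cells with 10 CPM (counts scaled to the summed UMIs of the cells) added. A marker counted as detected at 50 CPM or more and at 25% or more of its level in the highest cluster. A cluster took the name of a list with at least 3 genes among its leading genes, otherwise of the list with the largest share of its markers detected, leaving out the cycling list, which describes a state and not a type. It stayed unnamed with fewer than 100 cells, fewer than 3 detected markers, more leading markers of another class, no leading marker and no more markers detected than missing, or a low UMI count and no leading marker (the last decided no name). Clusters of the same name formed a class. No cluster took the name border-associated macrophage, although cluster 5 tied with it.

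Raw counts were summed per library and class (or cluster). CPM values refer to all UMIs of that sum. Sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment over all genes not used for clustering, threshold 0.05). Every named class with at least 50 cells per library entered one fit with the library as a block, which left 6 residual degrees of freedom. Clusters within a class were tested the same way over clusters of at least 100 cells per library, with 12 residual degrees of freedom, each microglia-like cluster against the mean of the others. Cluster 4 entered a fit of clusters of at least 50 cells per library, with 15 residual degrees of freedom. The spread therefore comes from all classes or clusters, since each has only 2 libraries. The block was set because both sides of each comparison come from the same libraries. The deviations of the replicates from their class means correlated across genes with r = 0.284 between macrophage-like and microglia-like cells (9761 genes) and r = 0.249 between monocyte-like and macrophage-like cells (7197 genes). Genes are not independent replicates.

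The 16 function lists held 324 genes: efferocytosis receptors, autophagy, lysosome, lipid handling, inflammatory mediators, chemokines, interferon response, antigen presentation, complement, glycolysis and hypoxia response, oxidative phosphorylation, regulatory and alternative activation, iron and oxidative stress, growth factors and matrix remodelling, regulatory T cell associated genes, and dissociation and immediate early genes. They were held out of the clustering so that they did not themselves define the clusters. Other genes that vary together with them were not held out. The grouping is therefore not independent of the lists, and p-values between clusters or classes may be too small. Each list was tested against the other genes with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation as an alternative) on logCPM with a prior count of 2. The fry test asked whether a list moved one way on balance, without comparing it with other genes. The 16 p-values of a comparison were adjusted together.

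The named genes of each comparison were, per list, up to 2 members with the largest rise and 1 with the largest fall (or 1 and 2 where more members fell) among those past the threshold with the same sign in both libraries. They are given for the comparisons of classes and in part for the clusters. Foxp3, Ptprc, Itgam, Adgre1 and Cd3e were named in every class, and so were the 3 most abundant markers of each class. Some of the genes these rules name are not reported here. Levels are means ± SD over the 2 libraries, log2 fold changes carry their standard error (SE), and shares of cells carry exact (Clopper-Pearson) 95% intervals. A count of 0 is given with the limit that 3 counts allow. Intervals and limits cover counting error only.

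The test was checked on simulated counts for the comparison of macrophage-like with microglia-like cells over 9877 genes, in 4 sets of 200 changed genes each. It recovered 282 of 448 genes changed 2-fold (62.9%) and 335 of 344 changed 4-fold (97.4%). Of 678 calls, 61 (9.00%) were false, and 3.99% of unchanged genes had an unadjusted p under 0.05. The false share exceeded the threshold of 0.05. Both simulated libraries of a class had the same profile, without a library effect or a clustering step. Far fewer genes changed than were called in the data, so the check does not cover these features of the data.

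Alternatives covered normalization by DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, no library block, a fit of only the 2 classes compared, subtraction of 10% free RNA, Leiden resolutions 0.4 and 1.2, looser (500 UMIs, 200 genes, 20% mitochondrial) and stricter (2000 UMIs, 1000 genes, 5% mitochondrial) cell filters, doublets kept, and each library left out in turn, which leaves differences of log2 CPM without a test. Thinning to 2000 UMIs per cell was used for the share of cluster 4. For Foxp3 it cannot change a count of 0. Leaving out cluster 5, weighting clusters equally, and comparing cluster 4, which has only 52 cells in replicate 2, were chosen after seeing the data. The comparison with border-associated macrophages and that of macrophages with and without Foxp3 were not run, since no cluster took the first name and no clustered cell had a Foxp3 UMI. Neither shows that such cells are absent.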

Results

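Single-cell transcript counts were collected from cells sorted as CD45+CD11b+CD3-F4/80+ (leukocytes with myeloid and macrophage surface markers and without the T cell marker) from the ischemic brain of Foxp3Egfp mice, in 1 group of 2 replicate libraries. There is no control group, so the comparisons are between kinds of cells within the libraries. After filtering, replicate 1 held 13624 cells with a median of 4975.5 UMIs and 1582 genes, and replicate 2 held 7409 cells with a median of 5612 UMIs and 1828 genes. Median mitochondrial shares were 1.92% and 1.58%. The summed profiles of the libraries correlated across 15967 genes with Pearson's r = 0.986 and Spearman's rho = 0.981 (genes are not independent replicates). Their counts differed by more than the sampling noise of UMIs, with a chi-square of 311 per degree of freedom, which says only that they are not the same counts deposited again.

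At the main resolution the largest class in both libraries resembled microglia, the resident macrophages of the brain. Microglia-like cells made up 44.4% of cells in replicate 1 (95% interval 43.6 to 45.3%) and 64.6% in replicate 2 (63.5 to 65.6%). Monocyte-derived macrophage-like cells, resembling macrophages that arise from blood monocytes, made up 34.3% (33.5 to 35.1%) and 8.91% (8.27 to 9.58%). Monocyte-like cells took 2.87% (2.60 to 3.16%) and 5.98% (5.45 to 6.54%), and neutrophil-like cells 5.39% (5.01 to 5.78%) and 7.95% (7.34 to 8.59%). The neutrophil-like class was mixed and also carried microglia transcripts (given below), so its share is not a share of neutrophils alone. Cycling-like cells took 5.38% (5.01 to 5.77%) and 3.12% (2.73 to 3.54%), dendritic cell-like cells 1.26% (1.07 to 1.46%) and 1.97% (1.67 to 2.31%), and T or NK cell-like cells 1.03% (0.872 to 1.22%) and 1.30% (1.05 to 1.58%). The remaining 5.30% (4.93 to 5.69%) and 6.22% (5.68 to 6.80%) lay in 7 clusters without a name. The sort and the UMI minimum can set these shares. They also depend on the resolution: at Leiden 1.2, replicate 1 had 22.2% microglia-like and 33.1% macrophage-like cells, and at Leiden 0.4 the macrophage-like share was 25.0% and 2.81%. The monocyte-like share was 12.5% and 11.9% at Leiden 0.4, 0.793% in replicate 1 with the stricter cell filter and 1.81% there with doublets kept, and the neutrophil-like share was 0.492% and 4.41% at Leiden 1.2. With the stricter filter T or NK cell-like cells took 0.506% in replicate 1. Cells without a name took 34.0% and 25.2% at Leiden 1.2, 1.81% in replicate 2 at Leiden 0.4, and in replicate 1 14.7% with the stricter filter and 14.1% with doublets kept. The spread between libraries was large for both main classes, with 54.5 ± 14.2% microglia-like and 21.6 ± 18.0% macrophage-like cells (mean ± SD, n = 2).

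**Figure D1:**
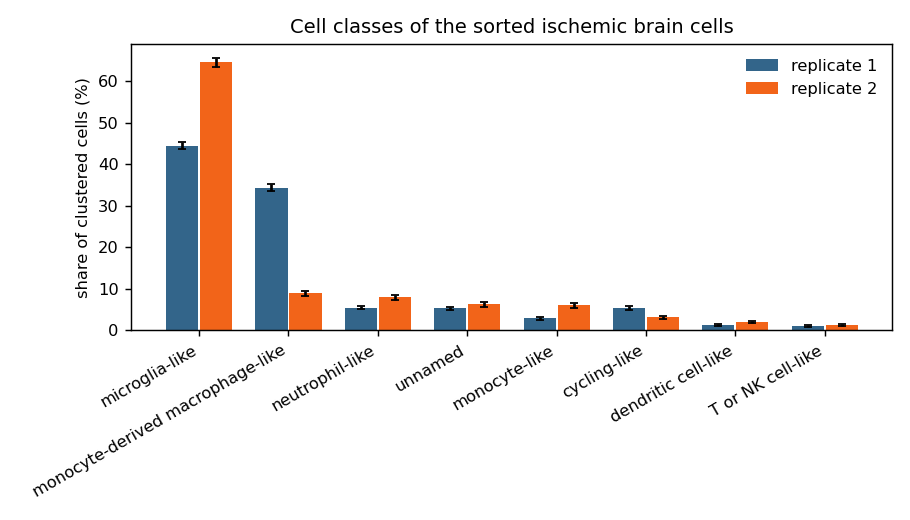
Share of clustered cells (%) in each class, with 1 bar per library and error bars for the exact 95% binomial interval. At this resolution microglia-like cells are the largest class in both libraries (44.4% and 64.6%; at Leiden 1.2 22.2% in replicate 1, below the macrophage-like 33.1%), and the macrophage-like share is 34.3% in replicate 1 and 8.91% in replicate 2.

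Each class carried its own markers. In microglia-like cells, Cst3 and Sparc stood at 40497 ± 4980 and 2236 ± 421 CPM (mean ± SD, n = 2 here and below). Lyz2, Lgals3 and Vim stood at 21639 ± 7635, 4608 ± 444 and 1136 ± 461 CPM in macrophage-like cells. Chil3, S100a4 and Plac8 stood at 2759 ± 884, 2275 ± 443 and 1834 ± 246 CPM in monocyte-like cells. S100a8, S100a9 and Camp, proteins of neutrophil granules and cytosol, stood at 25797 ± 15937, 24349 ± 15411 and 2341 ± 1677 CPM in neutrophil-like cells. S100a8 had a UMI in 96.6% and 97.3% of these cells and Camp in 6.13% and 4.41%, so the Camp level comes from a few cells. Neutrophil-like cells also held the summed microglia markers at 81.8% (replicate 1) and 49.3% (replicate 2) of the microglia-like level. Levels of this class are therefore those of a mixed class. Klrd1, Cd209a and Clec10a stood at 366 ± 41.7, 332 ± 97.7 and 157 ± 55.8 CPM in dendritic cell-like cells. Gzma, Nkg7 and Trbc2 stood at 1044 ± 561, 1034 ± 571 and 978 ± 638 CPM in T or NK cell-like cells. Birc5, Ube2c and Top2a, genes of cell division, stood at 403 ± 1.59, 353 ± 29.6 and 260 ± 5.27 CPM in cycling-like cells. These genes helped to define or name the classes and are not findings between them.

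Transcripts of Ptprc, Itgam and Adgre1, genes of markers used in the sort, were counted in every named class, in part at no more than their level in free RNA. Ptprc, which encodes CD45, stood at 216 ± 8.35 CPM in microglia-like, 133 ± 11.9 in macrophage-like and 411 ± 35.8 in monocyte-like cells. Itgam, which encodes CD11b, stood at 390 ± 16.3, 109 ± 26.3 and 293 ± 39.5 CPM, and Adgre1, which encodes F4/80, at 132 ± 10.6, 125 ± 11.1 and 75.8 ± 24.6 CPM in the same order. Neutrophil-like cells, a mixed class, held 374 ± 92.4, 418 ± 26.0 and 102 ± 23.7 CPM of Ptprc, Itgam and Adgre1. Dendritic cell-like cells held 305 ± 12.4, 187 ± 56.0 and 39.5 ± 21.4 CPM, and cycling-like cells 137 ± 7.51, 252 ± 42.6 and 120 ± 4.79 CPM. In T or NK cell-like cells, Ptprc, Itgam and Adgre1 stood at 599 ± 135, 177 ± 41.0 and 61.1 ± 23.4 CPM. Free RNA held Ptprc at 133 and 167 CPM, Itgam at 168 and 226 CPM, and Adgre1 at 124 and 99.4 CPM in the 2 libraries. In both libraries Ptprc (125 and 141 CPM) and Itgam (90.8 and 128 CPM) of macrophage-like cells and Adgre1 of monocyte-like cells (93.2 and 58.4 CPM) lay below these levels, and so did Ptprc of cycling-like cells and Adgre1 of neutrophil-like, dendritic cell-like and T or NK cell-like cells. This cannot tell whether these transcripts came from the cells or from free RNA, since the amount of free RNA per cell was not measured. Cd3e, a chain of the CD3 complex that the sort selected against, stood at 234 ± 73.2 CPM in T or NK cell-like cells, of which 40.4% (replicate 1, median 1940 UMIs) and 63.5% (replicate 2, median 3340 UMIs) had a Cd3e UMI, against no Cd3e UMI in 6054 and 4783 microglia-like cells (medians 3573 and 5161 UMIs).

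Foxp3, the factor whose reporter the mice carry, was not detected in any class. The gene (ENSMUSG00000039521, GRCm38 chromosome X, 7573644 to 7595245, plus strand) had 0 UMIs in 13624 cells of replicate 1 and 0 in 7409 cells of replicate 2, which allows a share of cells with a UMI of up to 0.0220% and 0.0405%, and a level of up to 0.0381 and 0.0573 CPM. For macrophage-like cells the limits were 0.0641% and 0.455%, for microglia-like cells 0.0496% and 0.0627%, and for T or NK cell-like cells, the class where Foxp3 would be sought first, 2.13% and 3.13%. The barcodes of at least 500 UMIs outside the clustered cells held 1 Foxp3 UMI, in replicate 1, among 4110 barcodes of both libraries. Free RNA held 1 Foxp3 UMI among 5004595 in replicate 1 and 0 among 2766383 in replicate 2, which allows up to 1.08 CPM. The single UMI amounts to 0.200 CPM, under the 0.599 CPM that 3 UMIs would give there. It lies above the limit of 0.0381 CPM over all cells but is too few to show a difference. A comparison of macrophages with and without Foxp3 could therefore not be made. The sort selected against CD3, and how reads from the reporter allele were counted was not examined. The limits therefore hold for counted Foxp3 UMIs alone.

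The first comparison set macrophage-like cells, of the kind the design text describes, against microglia-like cells. Macrophage-like cells were higher in lipid handling genes, of which 11 of 22 rose (camera adjusted p = 7.71e-05; adjusted p = 0.476 with an estimated correlation). Fabp4, a fatty acid chaperone (chromosome 3, 10204088 to 10208576, minus strand), had a log2 fold change of 6.56 ± 0.80 (SE, edgeR adjusted p = 4.2e-05), 94.2-fold higher. Cd36, a scavenger receptor for lipids and dying cells (chromosome 5, 17781690 to 17888801, minus strand), stood at 245 ± 185 against 5.78 ± 6.58 CPM, 51.1-fold higher (log2 fold change 5.68, 5.14 and 6.39 in the separate libraries, adjusted p = 5.73e-05). Arg1, the enzyme that splits arginine and a gene of alternative activation (chromosome 10, 24915221 to 24927484, minus strand), was 179-fold higher (448 ± 279 against 3.51 ± 3.25 CPM, adjusted p = 0.000239). Its log2 fold change of 7.48 was 5.38 in replicate 1 (251 against 5.81 CPM) and 8.80 in replicate 2 (645 against 1.21 CPM). Among macrophage-like cells Arg1 was far higher in cluster 5 than in clusters 4 and 7 (given below), so the class value rests mainly on cluster 5. That cluster held 1342 of 4678 macrophage-like cells in replicate 1 and 448 of 660 in replicate 2. Its markers tied with those of border-associated macrophages. Microglia-like cells were higher in Ch25h, which makes 25-hydroxycholesterol (log2 fold change −3.70 ± 0.32, adjusted p = 5.17e-06, chromosome 19, 34473778 to 34475164, minus strand). Ch25h is a leading gene of the microglia-like cluster 1 (800 and 198 cells), and it was not called with clusters weighted equally.

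Of 309 function genes tested, 129 were higher in macrophage-like cells and 65 in microglia-like cells (135 and 67 adjusted over the list alone), and 193 of these 194 had the same sign in both libraries. The calls and the classes come from these same libraries, so the shared sign is no separate evidence of agreement. Over all 9877 genes not used for clustering, 2122 were higher and 2106 lower. The lists that rose as a group were lipid handling (1 fell, median log2 fold change 1.08), with the sterol sensor gene Nr1h3 at 5.23 ± 0.47, and iron and oxidative stress (12 of 17 rose, 2 fell, median 1.84, adjusted p = 8.35e-06; adjusted p = 0.476 with an estimated correlation). In the iron list, Srxn1, which repairs oxidized peroxiredoxins, rose by 3.66 ± 0.31, and Hmox1, the heme-degrading enzyme, stood at 3338 ± 1498 against 320 ± 109 CPM (10.4-fold, log2 fold change 3.38, 2.52 and 4.18 in the separate libraries, adjusted p = 0.000203). The iron exporter gene Slc40a1 was lower at −0.70 ± 0.22. Oxidative phosphorylation rose in 16 of 20 genes with a median of 0.70 (adjusted p = 3.47e-07; adjusted p = 0.668 with an estimated correlation), with Cox5a at 1.30 ± 0.23 and Cycs at 1.27 ± 0.22. Glycolysis and hypoxia genes rose in 13 of 21, and 2 fell (median 1.01, adjusted p = 7.71e-05; adjusted p = 0.668 with an estimated correlation), with Ndrg1 at 4.55 ± 0.52 and the vessel growth factor Vegfa at 4.13 ± 0.42. The hexokinase gene Hk2 was lower at −1.71 ± 0.28. The lysosome list rose with a small median of 0.19 (10 of 27 rose, 1 fell, adjusted p = 0.0245; adjusted p = 0.785 with an estimated correlation). Its Atp6v0d2, a proton pump subunit, was higher at 6.47 ± 0.48, the acid lipase gene Lipa at 1.88 ± 0.27, and the protease gene Ctsl was lower at −0.95 ± 0.22. The interferon list rose in 9 of 22 genes, and 1 fell (median 0.73, adjusted p = 0.0135; adjusted p = 0.734 with an estimated correlation), with Ifitm3 at 1.64 ± 0.46, Oasl1 at 1.44 ± 0.39 and Gbp2 at −0.86 ± 0.30. The interferon median was −0.019 in replicate 1 and 1.40 in replicate 2, the lysosome median 0.61 and 0.072. In the separate libraries Oasl1 was 0.47 and 2.42, Ifitm3 0.56 and 2.51, and Gbp2 −1.19 and −0.33.

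Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were lower in macrophage-like cells (10 of 18 fell, 1 rose, median −0.88, −1.27 in replicate 1 and −0.52 in replicate 2, camera adjusted p = 7.85e-05; adjusted p = 0.676 with an estimated correlation). Egr1 (chromosome 18, 34859823 to 34864984, plus strand) stood at 108 ± 50.6 against 709 ± 168 CPM (log2 fold change −2.58, −3.52 and −2.04 in the separate libraries) and Btg2 at −2.11 ± 0.33 log2, while Rgs1 was higher at 0.83 ± 0.21. Inflammatory mediators moved with them, with 10 of 19 lower, 1 higher and a median of −0.85 (−1.42 in replicate 1 and −0.23 in replicate 2). The list missed the threshold (adjusted p = 0.067). Il1a was lower at −2.71 ± 0.46 and Il12b at −5.01 ± 0.85, the latter from 6 and 2 UMIs in macrophage-like cells. The receptor gene Clec4e was higher at 4.59 ± 0.76 (2.66 and 6.73 in the separate libraries). The chemokine list went both ways (9 of 20 rose, 4 fell, median 0.79, adjusted p = 0.584): Cxcl3 was higher at 6.13 ± 0.75 and Ccl7 at 4.09 ± 0.73 (2.66 and 5.09 in the separate libraries), and Ccl4 lower, at 670 ± 114 against 4479 ± 855 CPM.

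The other lists moved in no common direction. Efferocytosis receptors had 7 of 22 higher and 6 lower (median 0.10, with camera's direction down, adjusted p = 0.806), among them the scavenger receptor Msr1 at 2.94 ± 0.46 and the bridging protein gene Pros1 at −2.99 ± 0.33. Autophagy genes had 11 of 26 higher and 5 lower (adjusted p = 0.137), with the NADPH oxidase gene Cybb at 3.77 ± 0.53, Atg7 at 1.55 ± 0.24 and Map1lc3a at −1.21 ± 0.17. Antigen presentation had 7 of 17 higher and 3 lower (adjusted p = 0.43), with H2-Aa at 5.03 ± 0.85, H2-Eb1 at 4.79 ± 0.86 and Cd83 at −1.88 ± 0.34. Complement had 4 of 12 higher and 6 lower (adjusted p = 0.486), with Cfp at 5.81 ± 0.75 and C4b at −2.09 ± 0.37 (−2.69 and −1.18 in the separate libraries). Regulatory and alternative activation had 8 of 21 higher and 7 lower (adjusted p = 0.886), with Gpnmb 72.3-fold higher (log2 fold change 6.18, 5.29 and 6.66 in the separate libraries) and the cytokine signalling inhibitor Socs3 at −1.94 ± 0.30. Growth factor and matrix genes had 8 of 16 higher and 4 lower (adjusted p = 0.462), with Adam8 at 3.69 ± 0.70, Mmp12 at 3.40 ± 0.67 and Pdgfb at −2.96 ± 0.43. The regulatory T cell list had 2 of 9 higher and 3 lower (median 0.13, with camera's direction down, adjusted p = 0.636), with Ikzf2 at −2.49 ± 0.47. Nt5e, which encodes the ecto-enzyme CD73, had 111 UMIs in macrophage-like and 3 in microglia-like cells, a ratio of 56.2 (counting interval 18.7 to 277), with log2 fold changes of 3.37 and 4.73 in the separate libraries. Icos had 3 and 86 UMIs, a ratio of 18.9 (6.24 to 93.3) in favour of microglia-like cells, with −2.42 and −1.89 in the separate libraries. The separate-library values carry a prior count of 2, which shrinks differences at such low counts, so they can lie outside the counting intervals.

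Across these named genes the adjusted p ran from 3.69e-06 (Atp6v0d2, Nt5e) to 0.0325 (Gbp2). With camera's preset correlation 6 lists passed upwards and 1 downwards, with an estimated correlation 0 of 16 (1 at an unadjusted p under 0.05). The fry test gave 4 upwards: lipid handling and iron (adjusted p = 0.00497 each), oxidative phosphorylation (0.0157) and glycolysis (0.0268). Of the macrophage-like cells, cluster 4 holds 2390 of 4678 in replicate 1 and 52 of 660 in replicate 2, and cluster 5 holds 1342 and 448. Cluster 5 had as many leading markers of border-associated as of monocyte-derived macrophages. Without it, an alternative chosen after seeing the data, 93 genes were higher and 65 lower. Glycolysis (adjusted p = 0.676) and interferon (adjusted p = 0.209) no longer passed, inflammatory mediators passed downwards (adjusted p = 0.00208), and Hmox1 (0.046), Cxcl3 (0.74), Ccl7 (1.36), Ifitm3 (0.81) and Oasl1 (0.39) were not called. At Leiden resolution 0.4, Oasl1 (−0.035) and Hmox1 (−0.024) turned negative and were not called, and neither were Cxcl3 (0.89), Ccl7 (1.12) and Ifitm3 (0.48). The macrophage-like class held 3401 and 208 cells there and appears to have lost most of cluster 5, so this is no separate check. With clusters weighted equally, also chosen after seeing the data, Ch25h (−0.88) and Gbp2 (−0.18) were not called, and with free RNA subtracted as well Ch25h (−3.13), Gbp2 (−0.25), Cxcl3 (3.27) and Icos (−3.65) were not. Calls also ended for Gbp2 with DESeq2, for Gbp2 and Slc40a1 without the block, for Gbp2, Ifitm3 and Oasl1 with only the 2 classes fitted, for Slc40a1 with free RNA subtracted and for Oasl1 (0.76) at Leiden 1.2.

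**Figure D2:**
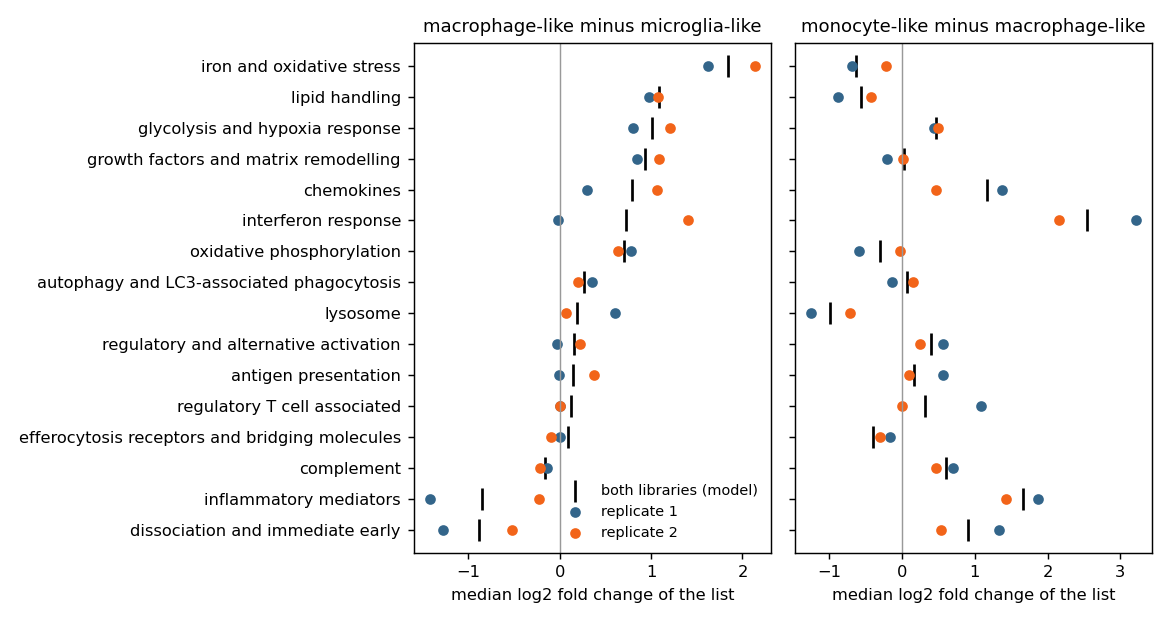
Median log2 fold change of each function list for both comparisons of classes, with points for the separate libraries and a black bar for the model over both. Iron and oxidative stress is highest for macrophage-like against microglia-like cells (1.84), and interferon response for monocyte-like against macrophage-like cells (2.54).

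The second comparison set monocyte-like cells against macrophage-like cells. The names rest on marker genes, and no origin was tested. Median depth was 2471 and 6492 UMIs in monocyte-like cells and 6465 and 8620 UMIs in macrophage-like cells (replicates 1 and 2). Monocyte-like cells were higher in interferon-induced genes, of which 20 of 22 rose (camera adjusted p = 1.07e-16; adjusted p = 0.195 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin (chromosome 12, 26442746 to 26456452, minus strand), stood at 588 ± 100 against 37.5 ± 5.55 CPM, 15.7-fold higher (adjusted p = 7.23e-05). Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889, minus strand), stood at 820 ± 191 against 50.8 ± 20.1 CPM (16.4-fold, adjusted p = 0.000465). The cytokine gene Il1b (chromosome 2, 129364570 to 129371139, minus strand) stood at 2911 ± 781 against 409 ± 405 CPM (8.22-fold, adjusted p = 0.00429). Its log2 fold change of 3.04 was 4.26 in replicate 1 and 2.32 in replicate 2. Macrophage-like cells were higher in Apoe, the lipid carrier (6.41-fold, adjusted p = 0.000228, chromosome 7, 19696109 to 19699188, minus strand), and in Igf1, a growth factor (20.5-fold, adjusted p = 9.25e-05, chromosome 10, 87858265 to 87937042, plus strand).

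Of the 309 function genes, 93 were higher in monocyte-like and 50 in macrophage-like cells (105 and 62 adjusted over the list alone), and all 143 had the same sign in both libraries. Here too the shared sign is no separate evidence of agreement. Over all 9877 genes, 962 were higher and 1055 lower. The interferon list had a median of 2.54, and 2 of its genes did not pass, with Cmpk2 at 3.72 ± 0.35. Inflammatory mediators rose in 15 of 19 (median 1.66, adjusted p = 8.17e-09; adjusted p = 0.195 with an estimated correlation), with Il6 at 3.18 ± 0.45. Immediate early genes of the dissociation list moved with these, with 10 of 18 higher and 1 lower (median 0.91, 1.33 in replicate 1 and 0.53 in replicate 2, adjusted p = 4.45e-06; adjusted p = 0.52 with an estimated correlation). Nr4a1 was higher at 2.30 ± 0.29, the heat shock gene Hspa1b at 2.04 ± 0.35 (3.04 and 1.31 in the separate libraries), and Rgs1 was lower at −1.57 ± 0.22. Lysosome genes fell in 20 of 27 (median −0.99, adjusted p = 6.28e-09; adjusted p = 0.52 with an estimated correlation), with the membrane protein gene Cd63 at −2.12 ± 0.21. Atp6v0d2 had 1 UMI in monocyte-like cells and 1481 in macrophage-like cells, a ratio of 163 (counting interval 29.2 to 6445). Chemokines rose in 8 of 20, and 2 fell (median 1.16, 1.37 in replicate 1 and 0.47 in replicate 2, adjusted p = 0.0126; adjusted p = 0.52 with an estimated correlation), with Cxcl9 at 2.61 ± 0.72 and Cxcl14 at −2.37 ± 0.45.

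Smaller shifts passed for glycolysis and hypoxia (8 of 21 rose, median 0.46, adjusted p = 0.00157; adjusted p = 0.525 with an estimated correlation), with the lactate transporter gene Slc16a3 at 1.81 ± 0.27 and Pfkp at 1.74 ± 0.40. They also passed for antigen presentation (6 of 17 rose, median 0.16, 0.56 in replicate 1 and 0.10 in replicate 2, adjusted p = 0.0156; adjusted p = 0.525 with an estimated correlation), with the costimulator Cd80 at 2.38 ± 0.37 and Ciita at 1.80 ± 0.52 (2.53 and 0.83 in the separate libraries). Regulatory and alternative activation rose in 7 of 21, and 2 fell (median 0.40, 0.56 in replicate 1 and 0.24 in replicate 2, adjusted p = 0.0221; adjusted p = 0.525 with an estimated correlation), with the interleukin 1 antagonist Il1rn at 2.66 ± 0.48, the checkpoint ligand Cd274 at 1.53 ± 0.32 and Igf1 at −4.36 ± 0.44. Oxidative phosphorylation passed downwards (median −0.30, −0.60 in replicate 1 and −0.023 in replicate 2, adjusted p = 0.0221; adjusted p = 0.626 with an estimated correlation), although 1 of its 20 genes passed by itself, Ndufb8 at −0.67 ± 0.20 (−0.97 and −0.38 in the separate libraries).

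Lipid handling did not pass as a list (3 of 22 rose, 7 fell, adjusted p = 0.143), with Dgat2 at 3.34 ± 0.45, Fabp5 at −2.68 ± 0.63 and Apoe at −2.68 ± 0.32. Iron and oxidative stress had 4 of 17 lower (adjusted p = 0.0973), among them the biliverdin reductase gene Blvrb at −1.09 ± 0.30 and Slc48a1 at −1.42 ± 0.27. Efferocytosis had 2 of 22 higher and 5 lower (adjusted p = 0.443), with the Fc receptor Fcgr1 at 1.26 ± 0.33, Trem2 at −1.77 ± 0.29 and Gas6 at −2.25 ± 0.40. Autophagy had 3 of 26 higher and 2 lower (adjusted p = 0.76), with Rb1cc1 at 0.84 ± 0.19, Uvrag at 0.71 ± 0.17 and Atg10 at −1.48 ± 0.30. Complement had 4 of 12 higher and 3 lower (adjusted p = 0.333), with C3 at 2.65 ± 0.42, Cfb at 1.87 ± 0.40 and C1qb at −1.41 ± 0.28. Growth factors had 4 of 16 higher and 3 lower (median 0.023, with camera's direction down, adjusted p = 0.956), with Lif at 3.23 ± 0.43, Mmp19 at 2.34 ± 0.36 and Gdf15 at −1.81 ± 0.38. In the regulatory T cell list 3 of 9 were higher (adjusted p = 0.356), among them Areg at 2.96 ± 0.75 (6 and 106 UMIs in monocyte-like cells, 1.34 and 2.91 in the separate libraries) and Nt5e at 1.56 ± 0.34.

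Named genes had adjusted p from 7.23e-05 (Rsad2, Cmpk2) to 0.0300 (Ndufb8). With camera's preset correlation 7 lists passed upwards and 2 downwards, with an estimated correlation 0 of 16 (2 at an unadjusted p under 0.05). The fry test gave interferon (adjusted p = 0.00506) and inflammatory mediators (0.0118) upwards and lysosome (0.0118) downwards. At Leiden resolution 0.4, where the monocyte-like class held 12.2% of cells (mean of the libraries) and was led by Arg1 and Hmox1 beside Chil3 and Plac8, 104 genes were called and 75 of them shared. There Slc48a1 (1.18, adjusted p = 0.00226) and Gdf15 (1.11, adjusted p = 0.0362) were called in the opposite direction, as was Slc40a1 (2.47 against −1.02, adjusted p = 0.00445), which the naming rule did not pick and which was chosen after its values were seen, and Blvrb (0.66) turned positive without a call. Another 12 of the 39 named genes were not called: Fcgr1 (0.82), Gas6 (−1.09), Rb1cc1 (0.56), Uvrag (0.072), Fabp5 (−0.22), Cxcl9 (1.38), Cxcl14 (−0.86), Ciita (0.97), Cfb (1.66), Ndufb8 (−0.19), Hspa1b (0.56) and Rgs1 (−0.30). Without cluster 5, which holds 448 of the 660 macrophage-like cells of replicate 2, 104 genes were higher and 47 lower, and antigen presentation (adjusted p = 0.218) and oxidative phosphorylation (adjusted p = 0.201) did not pass. This alternative was chosen after seeing the data. Of the 39 named genes, 7 were not called there: Cxcl9 (2.53), Ciita (1.46), Hspa1b (1.60), Ndufb8 (−0.55), Slc48a1 (−0.47), Blvrb (−0.58) and Gdf15 (−0.66). With the stricter cell filter 4 were not called: Uvrag (0.61), Ciita (2.58), Ndufb8 (−0.58) and Blvrb (−0.93). DESeq2 did not call Apoe (−2.64, adjusted p = 0.213). Calls also ended for Fabp5, Cfb, Ndufb8 and Gdf15 without the block, for Ciita and Ndufb8 with only the 2 classes fitted, for Fabp5 with free RNA subtracted, for Uvrag and Ndufb8 at Leiden 1.2, and for Fabp5 and Gdf15 with clusters weighted equally and free RNA subtracted.

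**Figure D3:**
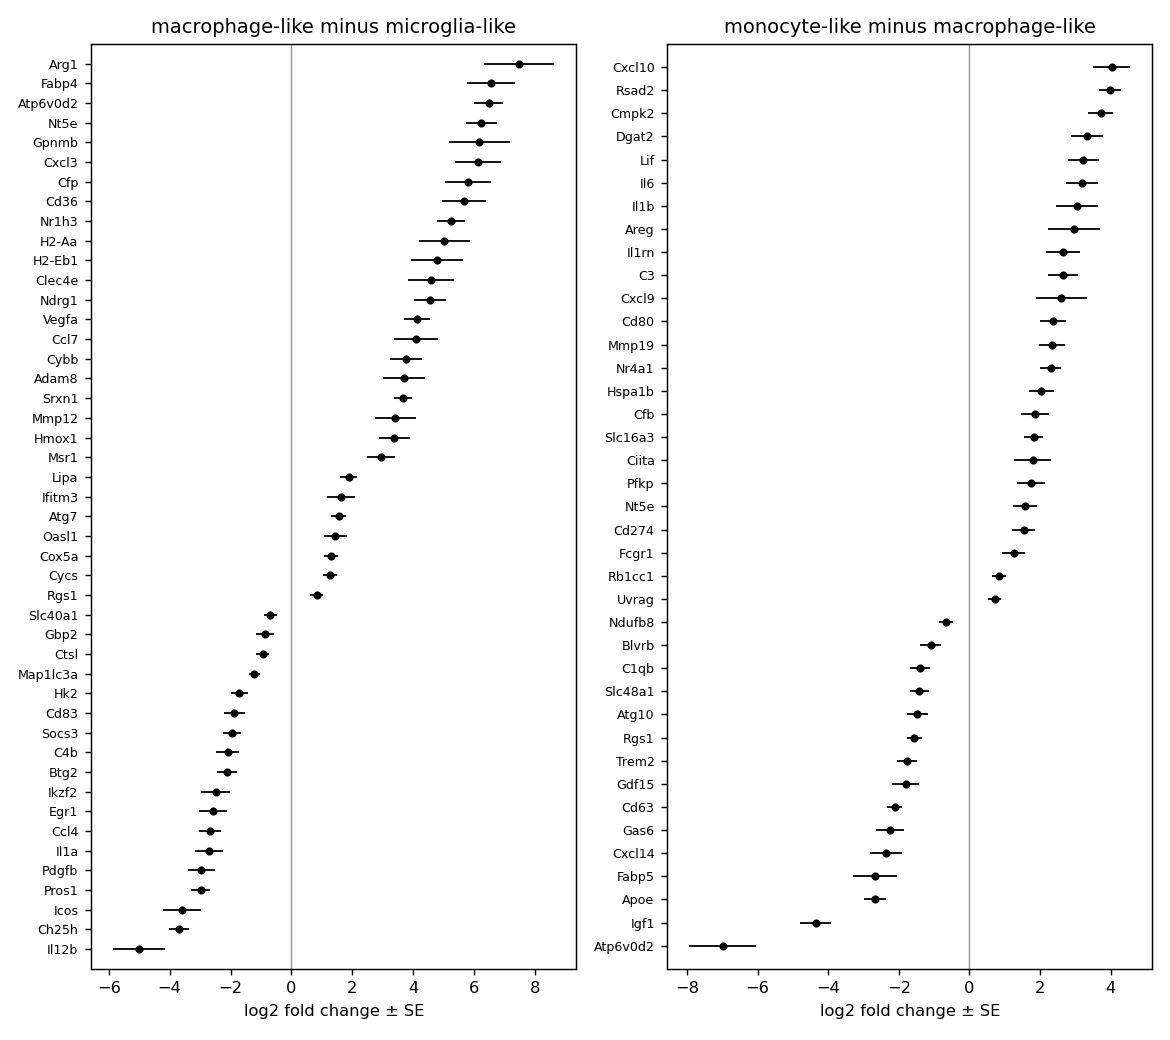
Log2 fold change ± SE of the reported genes named by the fixed rule, for both comparisons of classes, from the model over both libraries. Arg1 is highest (7.48) and Il12b lowest (−5.01) for macrophage-like against microglia-like cells. The Arg1 value rests mainly on cluster 5 of the macrophage-like cells. The values of Nt5e and Icos on the left and Atp6v0d2 on the right rest on 3 or fewer UMIs in the lower class and depend on the model's prior.

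The 6 microglia-like clusters were each compared with the mean of the other 5, for the function lists. Genes that vary with the lists could shape the clusters, so the p-values do not come from an independent grouping. Median depth (UMIs in replicates 1 and 2) was highest in clusters 1 (6381 and 13372) and 0 (5197.5 and 9183). It was lower in clusters 2 (3065 and 5702), 9 (2972 and 4138), 8 (1828 and 4293.5) and 3 (given below). Free RNA was not subtracted for clusters, and what depth adds to the differences was not tested. Cluster 0 (2100 and 922 cells; its leading genes include Ccl12, Tnf and Il1a) was higher in most of the lists: 13 of 16 passed upwards with camera and 8 with an estimated correlation. Interferon genes rose in 20 of 22 (median 1.35, camera adjusted p = 4.07e-40; adjusted p = 0.00196 with an estimated correlation), with Oasl1 at 2.25 ± 0.32 and Ifit1 at 2.07 ± 0.32. Inflammatory mediators rose in 10 of 19 (adjusted p = 0.000774 with an estimated correlation), with Il12b at 3.68 ± 0.45 (2.36 and 3.84 in the separate libraries) and Acod1, which makes itaconate, at 2.72 ± 0.54 (2.29 and 1.69). Chemokines rose in 9 of 20 (adjusted p = 0.000677 with an estimated correlation), with the B cell attractant Cxcl13 at 3.03 ± 0.65 (2.60 and 1.71 in the separate libraries). Lipid handling, antigen presentation and complement (adjusted p = 0.0116 each) and glycolysis and growth factors (adjusted p = 0.0386 each) also passed with an estimated correlation. Dissociation genes moved the same way, with 2 of 18 higher and a median of 0.32, 0.19 in replicate 1 and 0.46 in replicate 2 (camera adjusted p = 0.000103; adjusted p = 0.232 with an estimated correlation). In all, 64 function genes were higher in cluster 0 (109 higher and 2 lower adjusted over the list alone), and over all 10033 genes 141 were higher and 3 lower.

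Cluster 1 (800 and 198 cells, led by Ch25h, Cd5l and Cd72) was higher in genes of lipids, lysosome and energy metabolism. Lipid handling rose in 14 of 22 genes, and 3 fell (median 1.35, 0.81 in replicate 1 and 0.94 in replicate 2, camera adjusted p = 0.000314; adjusted p = 0.205 with an estimated correlation), with Ch25h at 5.91 ± 0.42. Lysosome genes rose in 19 of 27, and 1 fell (adjusted p = 1.83e-06; adjusted p = 0.341 with an estimated correlation), and oxidative phosphorylation in 17 of 20 (adjusted p = 3.67e-11; adjusted p = 0.253 with an estimated correlation). Interferon genes rose in 18 of 22 (median 1.02, 0.68 in replicate 1 and 1.2 in replicate 2, adjusted p = 6.02e-05; adjusted p = 0.341 with an estimated correlation). Glycolysis rose in 14 of 22, and 1 fell (adjusted p = 2.89e-05; adjusted p = 0.341 with an estimated correlation). The matrix protein gene Spp1 was higher at 4.45 ± 0.36, Mmp12 at 4.59 ± 0.71, Cxcl14 at 5.45 ± 0.21 and Msr1 at 3.20 ± 0.26. Dissociation genes fell in 17 of 18 (median −1.44, adjusted p = 3.35e-12; adjusted p = 0.205 with an estimated correlation), with Egr1 at −2.87 ± 0.36. Cluster 1 had 129 function genes higher and 59 lower (135 and 64 adjusted over the list alone), and 2467 and 2048 over all genes.

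Clusters 2, 3 and 8 also differed from the mean of the others in dissociation and immediate early genes, as clusters 0 and 1 did. Since that mean includes cluster 1, its fall adds to the rises in clusters 2 and 8. In cluster 2 (837 and 518 cells; its leading genes include Tnfaip3, Dusp1 and Ccl3) 14 of 18 rose (adjusted p = 2.86e-08; adjusted p = 0.314 with an estimated correlation), together with 10 of 19 inflammatory mediators (adjusted p = 0.000152; adjusted p = 0.314 with an estimated correlation). Tnf was higher there at 1.77 ± 0.16, Tnfaip3 at 1.71 ± 0.15, Dusp1 at 1.66 ± 0.17 and Cd300lf at 2.83 ± 0.24. Of 22 glycolysis genes 8 fell and 1 rose (median −0.49, −0.30 in replicate 1 and −0.65 in replicate 2, adjusted p = 4.87e-05; adjusted p = 0.36 with an estimated correlation). In cluster 3 (1211 and 529 cells) 11 of 18 dissociation genes fell and 2 rose (adjusted p = 2.61e-15; adjusted p = 0.0804 with an estimated correlation), with Fos at −1.62 ± 0.21 and Hspa1b at 1.64 ± 0.27. Of 19 inflammatory mediators 7 fell (adjusted p = 2.59e-15; adjusted p = 0.00543 with an estimated correlation), with Tnf at −2.06 ± 0.21 and Il1b at −2.51 ± 0.42. Its median depth was 1684 UMIs in replicate 1 and 4930 in replicate 2. In cluster 8 (361 and 460 cells; its leading genes include Klf2, Egr1 and Atf3) 14 of 18 dissociation genes rose (adjusted p = 2.21e-13; adjusted p = 0.128 with an estimated correlation), with Egr1 at 1.94 ± 0.25 and Atf3 at 1.61 ± 0.17. Interferon genes fell there in 12 of 22 (adjusted p = 8.12e-12; adjusted p = 0.128 with an estimated correlation), with Usp18 at −2.13 ± 0.46 (−1.24 and −2.20 in the separate libraries). Lysosome genes fell in 17 of 27 (adjusted p = 2.33e-10; adjusted p = 0.163 with an estimated correlation) and oxidative phosphorylation in 12 of 20 (adjusted p = 2.61e-11; adjusted p = 0.154 with an estimated correlation). Spp1, of the regulatory and alternative activation list, was lower at −2.98 ± 0.59. Function genes higher and lower numbered 66 and 14 in cluster 2 (73 and 18 adjusted over the list alone), 2 and 25 in cluster 3 (5 and 38), and 34 and 84 in cluster 8 (36 and 103). Over all genes they numbered 1045 and 585, 18 and 57, and 551 and 749.

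Cluster 9, led by the microglial receptor gene P2ry12 among others, held 5.47% of cells in replicate 1 (745) and 29.1% in replicate 2 (2156). It was lower in lipid, lysosome and energy genes. Lipid handling fell in 9 of 22 (median −1.04, −0.58 in replicate 1 and −0.69 in replicate 2, camera adjusted p = 1.15e-07; adjusted p = 0.0354 with an estimated correlation), with Apoe at −1.89 ± 0.24 and Apoc1 at −2.17 ± 0.25. Lysosome genes fell in 16 of 27 and oxidative phosphorylation in 13 of 20 (adjusted p = 5.17e-11 each; adjusted p = 0.167 with an estimated correlation for each). Interferon genes fell in 12 of 22 (median −0.97, −0.60 in replicate 1 and −0.99 in replicate 2, adjusted p = 2.31e-07; adjusted p = 0.167 with an estimated correlation). Igf1 was lower at −2.36 ± 0.32 and Hspa1b, which is also among the leading genes, higher at 1.80 ± 0.27. In the dissociation list 5 of 18 were higher and 1 lower (adjusted p = 0.398). Cluster 9 had 20 function genes higher and 112 lower (22 and 126 adjusted over the list alone), whereas over all genes 735 were higher and 1027 lower.

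**Figure D4:**
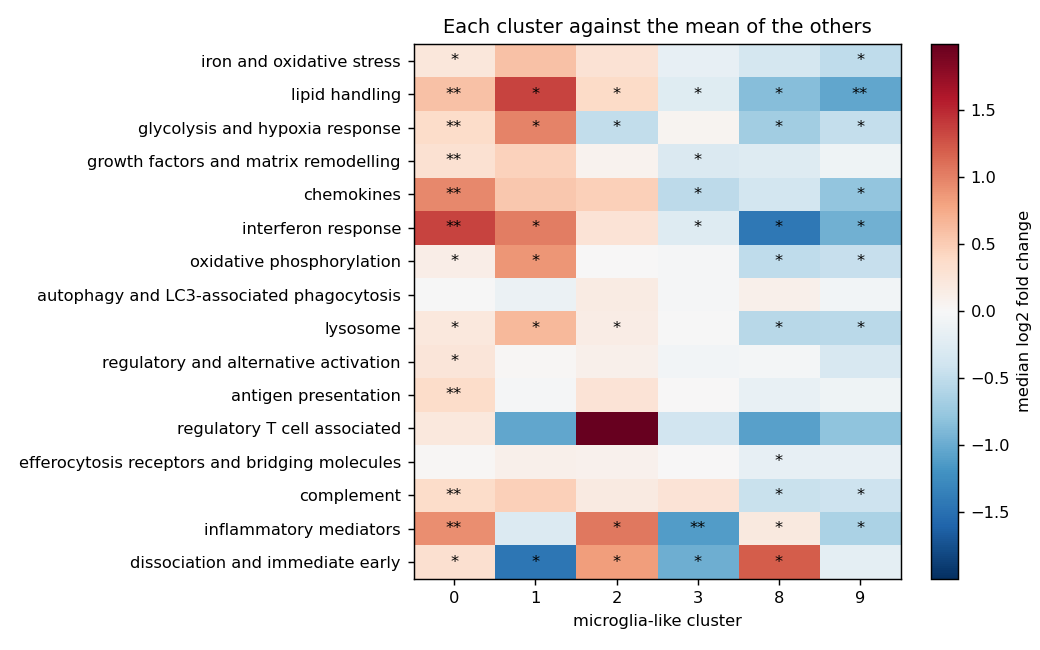
Median log2 fold change of each function list in each microglia-like cluster against the mean of the other clusters, from the model over both libraries. One star marks lists with a camera adjusted p under 0.05, and a pair of stars those that also pass with an estimated correlation. Interferon response is at 1.35 in cluster 0 and −1.43 in cluster 8, and the regulatory T cell list, with 6 genes tested, passed in no cluster.

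Among the macrophage-like clusters, 5 and 7 had enough cells in both libraries for the planned test (1342 and 448, 946 and 160 cells). Cluster 5, led by Arg1 and Hmox1, was higher in glycolysis and hypoxia genes (17 of 22 rose, median 1.49, camera adjusted p = 1.73e-14; adjusted p = 0.0806 with an estimated correlation) and in iron and oxidative stress genes (12 of 17 rose, 1 fell, adjusted p = 1.43e-08; adjusted p = 0.0887 with an estimated correlation). Oxidative phosphorylation rose in 10 of 20 (adjusted p = 5.65e-06; adjusted p = 0.4 with an estimated correlation). Arg1 was higher at 6.24 ± 0.65, Hmox1 at 4.82 ± 0.49, Cxcl3 at 6.43 ± 0.54 and Gclm, of glutathione synthesis, at 3.13 ± 0.31. Cluster 7, led by Cxcr4, Ifi203 and Mndal, was higher in antigen presentation (11 of 17, adjusted p = 8.04e-08; adjusted p = 0.0806 with an estimated correlation), with H2-Aa at −2.38 ± 0.43 for cluster 5 minus cluster 7 (−1.28 and −2.91 in the separate libraries), and in Apoe, at −1.84 ± 0.28. Dissociation genes moved with the second group, with 6 of 18 lower in cluster 5 and 1 higher (adjusted p = 0.0126; adjusted p = 0.6 with an estimated correlation). Altogether 82 function genes were higher in cluster 5 and 59 in cluster 7 (93 and 65 adjusted over the list alone), and over all 10033 genes 982 and 881.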

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

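The test of microglia marker UMIs per cell against T or NK cell-like cells and both tests of Xist were chosen after the results were seen. These patterns lie in neutrophil-like cells, which are on neither side of a comparison but add to the spread estimated in the fits, and in a cluster without a name.

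Neutrophil-like cells were a mixed class, and many carried transcripts of microglia: microglia marker UMIs per cell ran from 19.3 to 591 in replicate 1 and from 4 to 531 in replicate 2 (between the 10% of cells with fewest and the 10% with most), and at Leiden 1.2 a cluster of 623 and 243 cells with 14 of 14 microglia markers and 1 of 12 neutrophil markers detected stood apart from 67 and 327 neutrophil-like cells, although its leading genes included G0s2, Cxcr2 and S100a9 of the neutrophil list. Over the class, microglia markers summed to 42038 CPM in replicate 1, above the 20677 CPM of free RNA, and to 32086 CPM in replicate 2, where free RNA held 41785 CPM, so with ratios of 2.03 and 0.768 replicate 2 did not pass the bound set beforehand and free RNA as a whole stays open. Free RNA that adds a like number of UMIs to every droplet is argued against, since neutrophil-like cells had a median of 225.5 and 28 microglia marker UMIs against 4 and 3.5 in T or NK cell-like cells, a ratio of 56.4 and 8.0 (median depth 5658.5 and 3389 against 1940 and 3340 UMIs). The T or NK cell-like class was itself mixed. Its microglia markers summed to 25402 and 13801 CPM, 49.4% and 21.2% of the microglia-like level, and in replicate 1 this was above free RNA. Part of its cells therefore held far more than the median, and the pattern is not particular to neutrophil-like cells. Droplets with a randomly drawn second cell stay open as well. The macrophage share of the foreign RNA was 0.139 and 0.219 of its share in the library, below the bound set beforehand. The test counts all microglia RNA of the class as foreign, however. Any microglia grouped with the neutrophils would also lower this share, so it cannot decide. Selective contact, engulfment or sticking of neutrophils to microglia may contribute and stays open, and no biological explanation was tested.

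Cluster 12, which has no name, held cells with Xist, the RNA of the inactive X chromosome (X, 103460366 to 103483254, minus strand), which is expressed in cells of females. By the lower of the 2 libraries' folds over macrophage-like cells, Xist was followed by Pclaf, Marco, Ube2c, Saa3, Birc5 and Mrc1. Of these, Pclaf, Ube2c and Birc5 belong to the cycling list. Marco stood at 588 and 174 CPM, against 4.51 and 0 CPM in macrophage-like cells. Xist UMIs were found in 146 of 238 cells (61.3%) of replicate 1 and 8 of 17 (47.1%) of replicate 2, against 0.134% and 0.135% of the other cells, with median depths in the cluster of 8382.5 and 19170 UMIs. Free RNA is argued against, since the Xist level of 333 and 271 CPM was 50.4 and 93.9 times that of free RNA. Cells with a Xist UMI had Y-linked transcripts at 0.105 and 0.0344 of the level in macrophage-like cells, which is in line with female cells among male cells. Where such cells came from, for example a pooled animal or another source of cells, stays open, and no biological explanation was tested.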

How the results depend on the processing

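Leaving out cluster 5, weighting clusters equally and comparing cluster 4 were alternatives chosen after the data were seen. Log2 fold changes of the named genes kept direction and side of the threshold in 587 values for macrophage-like minus microglia-like cells (22 weaker, 2 reversed) and in 469 for monocyte-like minus macrophage-like (35 weaker, 3 reversed). These cover normalization, tool, count filter, block, classes in the fit, free RNA, resolution, cell filters and the alternatives on clusters, and none was run with doublets kept. For clusters, under normalization, tool, count filter and block, 1183 did so (108 weaker, 2 stronger, 3 with a changed sign and no call). List medians did so in 64 and 68 values for the class comparisons (10 and 11 weaker, 1 and 0 stronger, 5 and 1 with a changed sign and no call) under free RNA, block, cluster weights, cluster 5 and an estimated correlation, which leaves the median as it is, and in 230 for clusters (54 weaker, 2 stronger, 2 with a changed sign and no call) under the block and an estimated correlation. With 1 library left out there is no test: named genes stayed within the spread of the libraries in 83, 66 and 494 values and moved further in 11, 12 and 154, and list medians stayed in 23, 25 and 161, moved in 8, 7 and 126 and reversed in 1, 0 and 1. With 2 libraries, each lies within that spread of their mean whatever the values. Staying within it therefore shows no agreement between the libraries, and moving further reflects the step from their mean to the model's estimate. At Leiden resolution 0.4, Oasl1 (−0.035) and Hmox1 (−0.024) in the first comparison and Slc48a1 (1.18), Blvrb (0.66) and Gdf15 (1.11) in the second reversed (Slc48a1 and Gdf15 with a call). The macrophage-like class held 3401 and 208 cells there, against 4678 and 660 at the main resolution. The monocyte-like class held 1704 and 885, against 391 and 443. These shifts are close in size to cluster 5 (1342 and 448 cells), whose leading genes Arg1 and Hmox1 led the monocyte-like class there. Cluster 5 therefore appears to change class, and Leiden 0.4 is no check apart from leaving it out. Which cells moved was not examined. With 1 library left out, the interferon median ran from −0.019 to 1.40 for the first comparison and from −0.65 to 0.10 for cluster 3. Calls in the first comparison numbered 194 with DESeq2 size factors, 185 with DESeq2, 213 without a count filter, 193 with only the 2 classes fitted, 179 with free RNA subtracted, 174 and 199 at Leiden 0.4 and 1.2, 199 and 194 with looser and stricter cell filters, and 246 with clusters weighted equally. In the second they were 140, 137, 180, 157, 122, 104 and 140, 148 and 116, and 208. Without a count filter, where more genes are tested, clusters 0 and 3 had 117 and 56 calls. With no replicate block, calls fell to 165 and 101 for the class comparisons, to 40, 170, 49, 8, 74 and 75 for clusters 0, 1, 2, 3, 8 and 9, to 102 for cluster 5 minus 7, to 85 for 4 minus 5 and to 80 for 4 minus 7. There the lysosome list of the first comparison lost its camera call (adjusted p = 0.0883), as did efferocytosis (0.066) and inflammatory mediators (0.0541) in cluster 8 and lipid handling (0.103) in cluster 4 minus 7, while iron in cluster 3 (0.0239) and chemokines in cluster 5 minus 7 (0.0415) gained one, and no other list call changed. With an estimated correlation, lists past the threshold in limma's camera fell to 0 in both class comparisons (1 and 2 at an unadjusted p under 0.05), to 8, 0, 0, 1, 0 and 1 in clusters 0, 1, 2, 3, 8 and 9 (8, 3, 2, 4, 4 and 3 unadjusted), to 0 in cluster 5 minus 7 (3 unadjusted), to 5 in cluster 4 minus 5 and to 4 in cluster 4 minus 7 (6 unadjusted in each). Mean class shares moved to 36.1% microglia-like, 2.45% neutrophil-like and 29.6% unnamed at Leiden 1.2, to 12.2% monocyte-like, 13.9% macrophage-like and 2.76% unnamed at Leiden 0.4, to 0.821% T or NK cell-like and 10.4% unnamed with the stricter filter, and to 11.5% unnamed with doublets kept. Cells kept were 16504 and 8258 with the looser filter, 11835 and 7170 with the stricter one, and 11147 and 6053 with a minimum set from the top barcodes' UMIs. With 1 library alone, microglia-like shares ran from 44.4% to 64.6% and macrophage-like shares from 8.91% to 34.3%. The number and depth of T or NK cell-like cells limit what Foxp3 counts can show: 0 of 96 cells in replicate 2 allow a share with a UMI of up to 3.13%, and 0 of 53 in replicate 1 with the stricter filter up to 5.66%. The comparisons with border-associated macrophages and of cells with and without Foxp3 were not run, since no cluster took that name and no clustered cell had a Foxp3 UMI.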

Other observations

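The comparisons of cluster 4 and the correlation of its fold changes between libraries were chosen after the data were seen.

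Cluster 4, the macrophage-like cluster led by Gpnmb, Fabp4 and Lyz2, was lower than both other macrophage-like clusters in the interferon, inflammatory mediator and chemokine lists. Against cluster 5, 31 function genes were higher and 103 lower of 315 tested (48 and 121 adjusted over the list alone), whereas over all 11127 genes 460 were higher and 477 lower. Interferon genes were lower in 18 of 22 and higher in 1 (camera adjusted p = 9.46e-18; adjusted p = 0.0129 with an estimated correlation), inflammatory mediators lower in 13 of 19 (adjusted p = 0.0125 with an estimated correlation) and chemokines lower in 11 of 20 and higher in 1 (adjusted p = 0.00139 with an estimated correlation). Glycolysis was lower in 14 of 22 and iron and oxidative stress in 11 of 17 (adjusted p = 0.0129 with an estimated correlation for each), with Vegfa of the former at −2.79 ± 0.36 and Hmox1 of the latter at −4.05 ± 0.43. Dissociation genes moved with them, with 10 of 18 lower (adjusted p = 4.57e-09; adjusted p = 0.116 with an estimated correlation). Lysosome genes were higher in 11 of 27 (adjusted p = 2.36e-10; adjusted p = 0.177 with an estimated correlation). Outside these lists, Arg1 was lower at −5.52 ± 0.62 and the lipoprotein lipase gene Lpl higher at 1.97 ± 0.29. Against cluster 7, 47 were higher and 82 lower (70 and 98 adjusted over the list alone), whereas over all genes 599 were higher and 541 lower. Interferon genes were lower in 21 of 22 (adjusted p = 0.0293 with an estimated correlation), inflammatory mediators in 9 of 19 (adjusted p = 0.0449 with an estimated correlation) and chemokines in 7 of 20, with 1 higher (adjusted p = 0.0382 with an estimated correlation). Dissociation genes were lower in 15 of 18 (adjusted p = 0.0449 with an estimated correlation), with Egr1 at −3.03 ± 0.42. Oxidative phosphorylation was higher in 12 of 20 (adjusted p = 1.34e-11; adjusted p = 0.114 with an estimated correlation), with Ndufa1 at 0.87 ± 0.19. Outside these lists, Cd36 was higher at 3.08 ± 0.37 and Fabp4 at 2.55 ± 0.42 (2.33 in replicate 1 and 4.0 in replicate 2). These values rest on 2390 cells of replicate 1 and 52 of replicate 2.

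The clusters without a name were led by genes of several kinds. Cluster 16 (153 and 94 cells) was led by the collagen genes Col3a1 and Col1a1 with Apod and Igfbp7, and cluster 19 (67 and 6 cells) by Nov, Penk and Ogn. Cluster 17 (31 and 1 cells) was led by Mt3, Tmem212 and Ccdc153, cluster 20 (17 and 18 cells) by the antibody genes Igkc, Igha and Jchain with Cd79a, and cluster 21 (27 and 12 cells) by Ttr, Ptgds and Enpp2. Cluster 14 (189 and 313 cells) was led by Cox6a2, Saa3, Cd72 and Afp and had 10 of 14 microglia markers detected.

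Cluster 4 was mostly in replicate 1, with 51.1% of macrophage-like cells there and 7.88% in replicate 2. After thinning to 2000 UMIs and renewed assignment the shares were 55.6% and 11.5%, a ratio of 4.85, above the bound set beforehand. Unequal depth at the step of assignment is therefore argued against. The cells were assigned to the clusters found at full depth, however, and 85.2% returned to their own. A depth effect on the clustering itself would be carried along, so it stays open. A library-wide shift that splits 1 cell state stays open. The fold changes of cluster 4 minus cluster 5 in the separate libraries correlated across 315 function genes with Pearson's r = 0.838 (Spearman's rho = 0.824), but both clusters were defined on the cells of both libraries together, so this cannot decide. A difference between the animals, the time after stroke or the gate of the sort may set the share and stays open, since the labels describe both libraries alike and no biological explanation was tested.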
